A study of Mus musculus with 19 samples.

How the data were processed

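RNA was measured by bulk sequencing in 19 libraries of mouse organoids, 3-dimensional cell cultures: normal lung (n = 3), non-small cell lung cancer (NSCLC, n = 4), NSCLC sensitive to immunotherapy (n = 3) and NSCLC resistant to immunotherapy (n = 9). Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced as paired reads on a NovaSeq instrument. The submitters' processing notes name the aligner STAR 2.6.0a, the tool DESeq2 1.26.0 and the mouse build mm10. The read counter and the gene annotation are not given in the sources used here. The authors deposited one table for normal and NSCLC and another for sensitive and resistant. Each holds whole-number read counts per gene and library, not normalized, per the file headers and the values. The deposited tables also hold the authors' log2 fold changes and adjusted p-values. Log2 values per library in the resistant table equal the log2 of the count over a size factor plus 1, and were not used further. The scaled columns of the NSCLC table have a unit that could not be settled from the values and were not used here.

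Each table was analysed on its own, so no level was compared across tables. In the NSCLC table, 26857 Ensembl identifiers without a symbol were given one from the reference gene names, and 26 symbols stored as dates were restored through their Entrez numbers. For resistant and sensitive libraries, 26 of 27 such symbols were restored. For 151 repeated symbols the row with the most counts kept the plain name. Genes with too few counts were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3), and libraries were scaled by TMM. Groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment, with adjusted p under 0.05 as the threshold. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic. CPM values are counts over the TMM-scaled library size, given as mean ± SD. A fold against a group with no counts is a lower bound, taken against 3 counts in the shallowest library of that group. Positions are from the GENCODE annotation of the same mouse build, with ends counted from 1.

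The 39 gene lists, the tests of the comparisons, the alternatives other than thinning, leaving out 3 resistant libraries together and averaging close pairs of resistant libraries, and the rule for named genes were written before the data were examined. Lists with at least 5 tested members were tested with fry of limma 3.58.1 on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over lists. Fry asks whether a list's members moved one way on balance and does not compare a list with other genes. Limma's camera with an estimated correlation, which does compare with other genes, passed 0 lists in either comparison. Its adjusted p is given beside each list described in detail. Camera with a preset correlation of 0.01 also compares with other genes. It ended 8 of the 27 fry calls in NSCLC and 5 of the 21 in resistant. For collagens its adjusted p was 1.71e-06 in NSCLC and 6.71e-05 in resistant. Whether lists stood out against other genes thus depended on the correlation setting. The symbols written for mitochondrially encoded genes matched no row, since the NSCLC table names these genes otherwise (COX1, for example), so that list was not tested. Where a list held genes with 0 counts in a group, its median log2 fold change was also taken with those genes at their bound. A list score is the mean log2 CPM over the tested members. Differences in the collagen score were tested by exact two-sided permutation of libraries, and relations between scores within the resistant group by exact permutation of pairings, with adjustment over the 7 relations computed. Named genes were chosen by a rule in 3 parts. The first took the 8 genes with the largest fold change in each direction among those past the threshold, with a mean log2 CPM of at least 3, groups that did not overlap and a symbol other than an unnamed gene model or pseudogene. The others took up to 3 members with the smallest adjusted p of each list that passed, and a fixed set of collagen, antigen presentation and lineage genes. Where the text names a gene outside the rule, it says that the gene was chosen after its values were seen. Some genes that meet the rule are not reported here.

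Nothing in the labels says that libraries came from separate animals or cultures, so p-values measure the spread between these libraries only, which may be technical. Sex-linked reads differed among the resistant libraries, so the spread in that group is not only technical. No pair of libraries in a group was identical or differed by as little as counting noise. Total counts ran from 20138197 to 21060762 per normal library and from 122967042 to 154479953 per NSCLC library. They ran from 15292427 to 18716749 per sensitive library and from 11988677 to 24462955 per resistant library. Depth therefore goes with the group in the NSCLC comparison, and the comparison was repeated with all libraries thinned to the smallest total. On simulated counts with the real means and depths, 74% of genes changed 4-fold and 16% of genes changed 2-fold were called in the NSCLC design, with 2 false calls among 19932 genes. In the resistant design the shares were 66% and 22%, with 7 false calls among 14360 genes. Each simulation changed 50 genes at each of 1.5-, 2-, 4- and 8-fold, far fewer genes than were called in the data. The adjusted threshold was therefore stricter in the simulations, and these shares are not those of the real comparisons. Under TMM the median log2 fold change over all tested genes was 0.11 for NSCLC over normal and under upper quartile scaling -0.08. Fold changes and counts are given as fitted, without subtracting that median. Other settings tried were DESeq2 1.42.0, limma-voom, other scalings, filters and thresholds, a replicate block, and leaving out each library in turn.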

Results

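The series measured gene expression in mouse lung organoids in 4 groups, which give 2 comparisons: NSCLC against normal lung, and immunotherapy-resistant against immunotherapy-sensitive NSCLC. The series title names collagens expressed by cancer cells as a physical barrier in acquired resistance, so collagen genes were followed in both comparisons. NSCLC libraries held 122967042 to 154479953 counts and normal libraries 20138197 to 21060762. Sensitive libraries held 15292427 to 18716749 and resistant libraries 11988677 to 24462955.

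Alveolar genes were lower in NSCLC organoids than in normal lung organoids, and gut endoderm, glycolytic and cell cycle genes were higher. Sftpc encodes surfactant protein C of alveolar type 2 cells and lies on chromosome 14 from 70520949 to 70524081 (mm10). It was the most abundant gene of each of the 3 normal libraries at 38546 ± 3662 CPM (SD, n = 3) and fell to 2343 ± 547 CPM in NSCLC (n = 4; log2 fold change -4.04 ± 0.30 SE, adjusted p = 2.52e-05, edgeR quasi-likelihood test). Nkx2-1, the transcription factor of lung epithelial identity, fell from 860.3 ± 114 CPM to between 124 and 215 CPM. Hnf4a, a transcription factor of gut and liver epithelium, rose from 0.183 ± 0.141 to 279 ± 145 CPM (log2 fold change 10.57 ± 0.89 SE, adjusted p = 4.34e-05). Across genes, 5672 were higher and 4983 lower in NSCLC among 19932 tested. Which direction held more genes depended on the setting, with 4681 higher and 5758 lower under upper quartile scaling. Without regard to direction, 59.4% of tested genes had groups that did not overlap, against 5.71% by chance. The authors' deposited table lists 5715 genes higher and 5757 lower at the same threshold. Of the 10655 edgeR calls 10357 were shared with it, with 0 of opposite sign.

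Several lists of lung cell markers were lower. Of 24 alveolar type 2 genes tested, 18 fell and 0 rose (fry adjusted p = 5.53e-05; adjusted p = 0.258 with an estimated correlation). Among them, Abca3, the lamellar body lipid transporter, fell from 1740.5 ± 139 to 166 ± 37.9 CPM, and Lpcat1, an enzyme of surfactant lipid synthesis, from 2629.9 ± 68.4 to 107 ± 25.8 CPM. In the alveolar type 1 list 14 of 20 genes fell (fry adjusted p = 0.00424, and 0.00158 to 0.071 over all fry alternatives; adjusted p = 0.425 with an estimated correlation), including Pdpn, podoplanin (log2 fold change -6.69 ± 0.69 SE, adjusted p = 1.29e-04). Club and goblet genes went both ways, with 10 lower and 3 higher of 19 (fry adjusted p = 0.00719; adjusted p = 0.425 with an estimated correlation). Scgb3a2 had 0 counts in NSCLC and was at least 525-fold lower, while Agr2 rose to 86.6 ± 62.5 CPM. The ciliated list had 11 lower and 2 higher of 18 (fry adjusted p = 0.00111; adjusted p = 0.371 with an estimated correlation). Foxj1, the regulator of motile cilia, was at 8.76 ± 4.89 CPM in normal and 0.323 ± 0.318 CPM in NSCLC. The largest falls by the rule were of Sec14l3, Pxdn, a collagen IV crosslinking peroxidase, Col4a4, Limch1, Igfbp5, Saa3, Ces1d and Akr1c14, with log2 fold changes from -10.76 to -7.71.

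Gut endoderm genes rose, with 18 of 23 higher and 0 lower and a median log2 fold change of 7.22, or 5.84 with 5 genes at 0 counts in a group set to their bound (fry adjusted p = 2.92e-04; adjusted p = 0.342 with an estimated correlation). Among the largest rises by the rule were those of Apoa1, Hnf4a, Gpa33, Tns4, Angptl4, Onecut2 and Itga2. Besides Hnf4a the gut list included Lgals4 and Vil1, which encodes the brush border protein villin, at 0.229 ± 0.141 CPM in normal and 142 ± 79.4 CPM in NSCLC. The gut-type surface antigen gene Gpa33 rose to 175 ± 71.9 CPM, and Apoa1, an apolipoprotein gene of liver and gut, ranged from 8.18 to 1466 CPM over the NSCLC libraries (log2 fold change 11.62 ± 2.05 SE, adjusted p = 0.00191). In the embryonic and high plasticity tumour list 14 rose and 1 fell of 23, among them Hmga2 (log2 fold change 3.50 ± 0.31 SE, adjusted p = 5.37e-05), Sox9 and the integrin gene Itga2 (fry adjusted p = 2.51e-04; adjusted p = 0.342 with an estimated correlation). Epithelial adhesion and keratin genes rose in 18 of 27 cases and fell in 2 (fry adjusted p = 6.41e-04; adjusted p = 0.425 with an estimated correlation). Krt8 was at 2909.9 ± 428 CPM against 313 ± 76.1 in normal, and Epcam at 500.2 ± 69.8 against 113 ± 3.03.

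**Figure D1:**
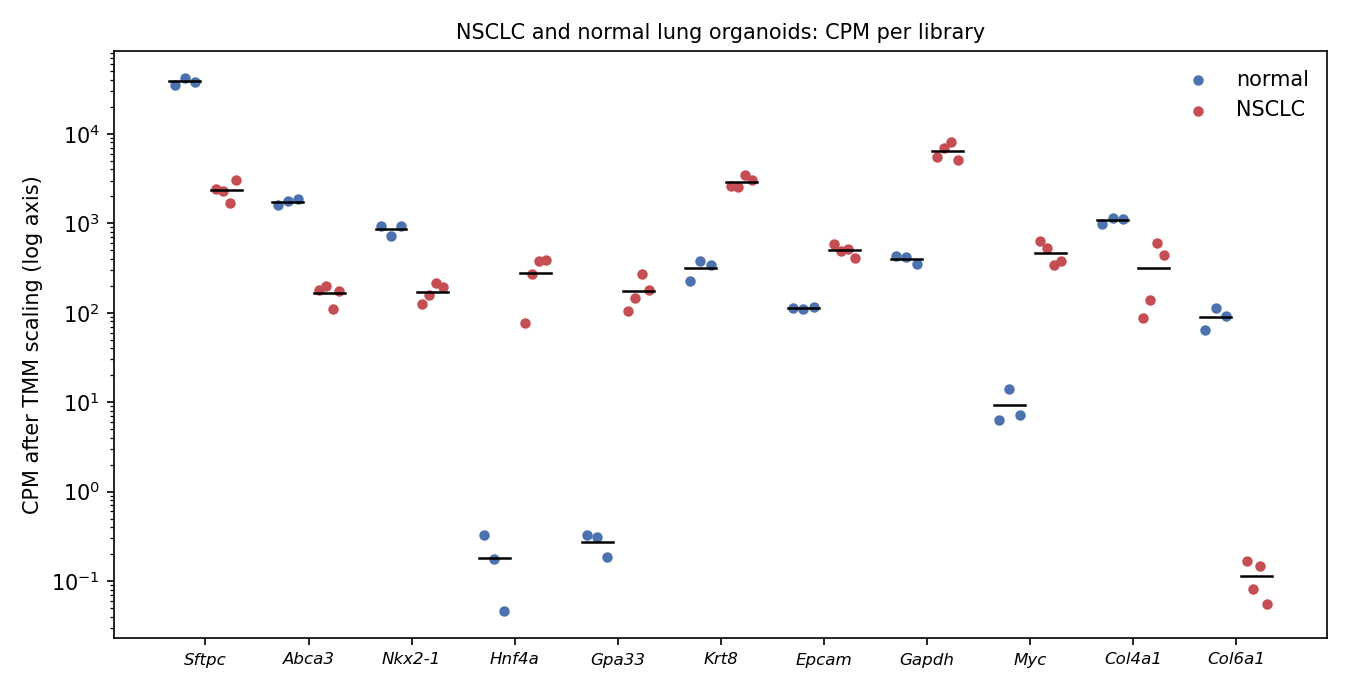
Each point is a library's CPM after TMM scaling (log axis) for a gene named on the horizontal axis, in normal (blue, n = 3) and NSCLC organoids (red, n = 4), and black lines are group means. Sftpc was 38546 CPM on average in normal and 2343 in NSCLC, and Hnf4a 0.183 and 279.

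Growth-related groups were higher in NSCLC. Of 38 proliferation genes 37 rose and 0 fell, Aurkb and Cdt1 among them, with a median log2 fold change of 2.05 (fry adjusted p = 0.00397, and 0.00371 to 0.071 over all fry alternatives; adjusted p = 0.425 with an estimated correlation). With a replicate block the calls of the proliferation, alveolar type 1 and macrophage lists were lost. In the hypoxia and glycolysis list 25 of 30 rose and 1 fell; Gapdh, a glycolytic enzyme, went from 397 ± 43.1 to 6411 ± 1409 CPM (fry adjusted p = 2.92e-04; adjusted p = 0.371 with an estimated correlation). Genes of RAS and ERK output rose in 16 of 24 cases and fell in 2 (fry adjusted p = 1.84e-04; adjusted p = 0.342 with an estimated correlation). Myc rose from 9.19 ± 4.28 to 471 ± 138 CPM, while Spry1, a feedback inhibitor of the pathway, fell (log2 fold change -1.73 ± 0.12 SE, adjusted p = 1.43e-05). Targets of p53 fell in 16 of 30 cases and rose in 6, with Phlda3 and Ccng1 lower (fry adjusted p = 0.00107; adjusted p = 0.425 with an estimated correlation). Trp53 itself was at 25.3 ± 6.47 CPM in normal and 11.2 ± 2.7 in NSCLC (log2 fold change -1.18 ± 0.25 SE, adjusted p = 0.00474).

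Collagen genes were lower in NSCLC than in normal organoids. Of 35 tested, 21 fell and 2 rose over all genes tested, and 22 fell and 2 rose adjusted over the list alone, with a median log2 fold change of -3.16 (fry adjusted p = 1.84e-04; adjusted p = 0.342 with an estimated correlation). Col1a2 and Col3a1, fibrillar collagen chains, went from 52.2 ± 57.5 and 62.1 ± 80.9 CPM to 0.0127 ± 0.0101 and 0.00904 ± 0.0132 CPM. Normal library 2 held the highest values of both genes among the normal libraries. Col5a2 had 0 counts in NSCLC and was at least 802-fold lower. Col4a1, a basement membrane collagen, was at 1076 ± 91.2 CPM in normal and 316 ± 244 CPM in NSCLC (log2 fold change -1.77 ± 0.60 SE, adjusted p = 0.0369), a call lost without normal library 1, 2 or 3 or NSCLC library 2. The genes that rose were Col11a2 and Col20a1, named after their values were seen. The collagen score was 2.79 ± 0.32 in normal and -1.17 ± 0.33 in NSCLC, a difference of -3.96 (exact two-sided permutation p = 0.0571, the smallest that 35 regroupings can give). Fibroblast and macrophage markers went the same way. Of the fibroblast markers without collagens, 17 of 22 fell and 0 rose (fry adjusted p = 1.84e-04; adjusted p = 0.342 with an estimated correlation). Pdgfra was at 37 ± 34 CPM in normal and 0.0642 ± 0.0396 in NSCLC. Macrophage markers fell in 18 of 26 cases and rose in 3 (fry adjusted p = 0.00525, and 0.00332 to 0.0653 over all fry alternatives; adjusted p = 0.425 with an estimated correlation).

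MHC class I genes, which present antigen to T cells, did not pass the test in this comparison (7 higher and 5 lower of 24; fry adjusted p = 0.895), and B2m was at 143 ± 66.2 CPM in normal and 145 ± 66.5 in NSCLC.

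Resistant organoids expressed collagen and mesenchymal genes at higher levels than sensitive organoids and epithelial genes at lower levels. Twist1, a transcription factor of mesenchymal transition, was at 0.102 ± 0.0376 CPM in sensitive (SD, n = 3) and 126 ± 21.6 CPM in resistant organoids (n = 9), with each resistant library at 89.5 CPM or more (log2 fold change 10.19 ± 0.34 SE, adjusted p = 2.39e-09, edgeR quasi-likelihood test). Col6a1 rose from 1.84 ± 0.371 to 158 ± 91.6 CPM (log2 fold change 6.42 ± 0.68 SE, adjusted p = 2.87e-05). Krt8, a simple epithelial keratin, fell from 1322 ± 153 to 236 ± 92.3 CPM (log2 fold change -2.49 ± 0.27 SE, adjusted p = 3.75e-05). Among 14360 genes tested, 2768 were higher and 2612 lower in resistant. Without sensitive library 3 the count of higher genes was 1765, and without sensitive library 1 it was 1800. Groups did not overlap for 31.3% of tested genes, against 0.909% by chance. The authors' deposited table lists 3242 genes higher and 3026 lower, and 5323 of the 5380 edgeR calls were shared with it.

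Of 32 collagen genes tested, 16 rose and 2 fell over all genes tested, and 17 rose and 2 fell adjusted over the list alone, with a median log2 fold change of 2.36 (fry adjusted p = 9.25e-04; adjusted p = 0.449 with an estimated correlation). Over all fry alternatives the adjusted p of this list ran from 3.13e-05 to 0.0577, and its call was lost with a replicate block. The fibrillar chain Col3a1, on chromosome 1 from 45311538 to 45349706 (mm10), rose from 3.63 ± 3.5 to 146 ± 53.5 CPM (log2 fold change 5.32 ± 0.81 SE, adjusted p = 3.59e-04). Col1a2 rose from 3.12 ± 0.739 to 96.8 ± 60.7 CPM and Col5a1 from 6.54 ± 3.62 to 122 ± 43.7 CPM. Col1a1 varied widely, from 4.07 to 426 CPM over the resistant libraries (log2 fold change 5.27 ± 1.74 SE, adjusted p = 0.0298), and its call was lost without any of sensitive libraries 1, 2 or 3. Col26a1 fell from 9.5 ± 2.99 CPM to 0.133 CPM or less, with 3 counts in the whole resistant group. Col4a6, named after its values were seen, also fell. The basement membrane chains Col4a1 and Col4a2 did not pass the test, at 127 ± 70.2 and 128 ± 66.4 CPM in resistant against 132 ± 36.3 and 85.4 ± 14.9 CPM in sensitive. The collagen score was 0.94 ± 0.36 in sensitive and 3.10 ± 0.66 in resistant, a difference of 2.16, with each of the 9 resistant libraries above each of the 3 sensitive libraries (exact two-sided permutation p = 0.00909, the smallest that 220 regroupings can give).

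Genes that process and surround collagen rose as well. In the collagen processing and crosslinking list 15 of 28 rose and 0 fell (fry adjusted p = 1.37e-05; adjusted p = 0.306 with an estimated correlation). Pcolce, an enhancer of procollagen cleavage, was at 13.1 ± 0.257 CPM in sensitive and 273 ± 114 CPM in resistant. Lox, a collagen crosslinking enzyme, ranged from 1.39 to 229.6 CPM over the resistant libraries and did not pass the test (log2 fold change 2.79 ± 1.48 SE, adjusted p = 0.153). Basement membrane and matrix glycoprotein genes rose in 21 of 32 cases and fell in 4 (fry adjusted p = 3.88e-05, and 1.61e-06 to 0.0621 over all fry alternatives, lost with a replicate block; adjusted p = 0.413 with an estimated correlation), including the perlecan gene Hspg2 (log2 fold change 4.97 ± 0.37 SE, adjusted p = 3.30e-06). Fbn2, which encodes fibrillin-2, had 1 count in the sensitive group and 115 ± 54.1 CPM in resistant. Ddr1, a collagen receptor kinase gene, fell from 92 ± 4.99 to 46.9 ± 13.9 CPM.

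Mesenchymal transition genes rose in 12 of 22 cases and fell in 0 (fry adjusted p = 2.17e-07; adjusted p = 0.213 with an estimated correlation). Vim, the intermediate filament vimentin, went from 136 ± 98.6 to 2182 ± 875 CPM, Axl, a receptor tyrosine kinase gene, from 11.7 ± 6.19 to 625 ± 209 CPM, and Zeb1 from 1.7 ± 1.06 to 63.1 ± 14.1 CPM. By the rule on fold change, Fbn2, Mgp, Twist2, Adamts14, Mrc2, a collagen uptake receptor gene, and Flnc were also among the largest rises, with log2 fold changes from 7.77 to 11.25 for those other than Fbn2. Fibroblast markers without collagens rose in 10 of 16 cases and fell in 1 (fry adjusted p = 0.0082; adjusted p = 0.523 with an estimated correlation); Pdgfra was at 2.47 ± 1.74 CPM in sensitive and 89.1 ± 89.2 in resistant. Without resistant libraries 6, 8 and 9, which held Xist reads and no Y-linked reads, the fibroblast list had a fry adjusted p of 0.0518. Over all fry alternatives its adjusted p ran from 0.00178 to 0.0518.

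**Figure D2:**
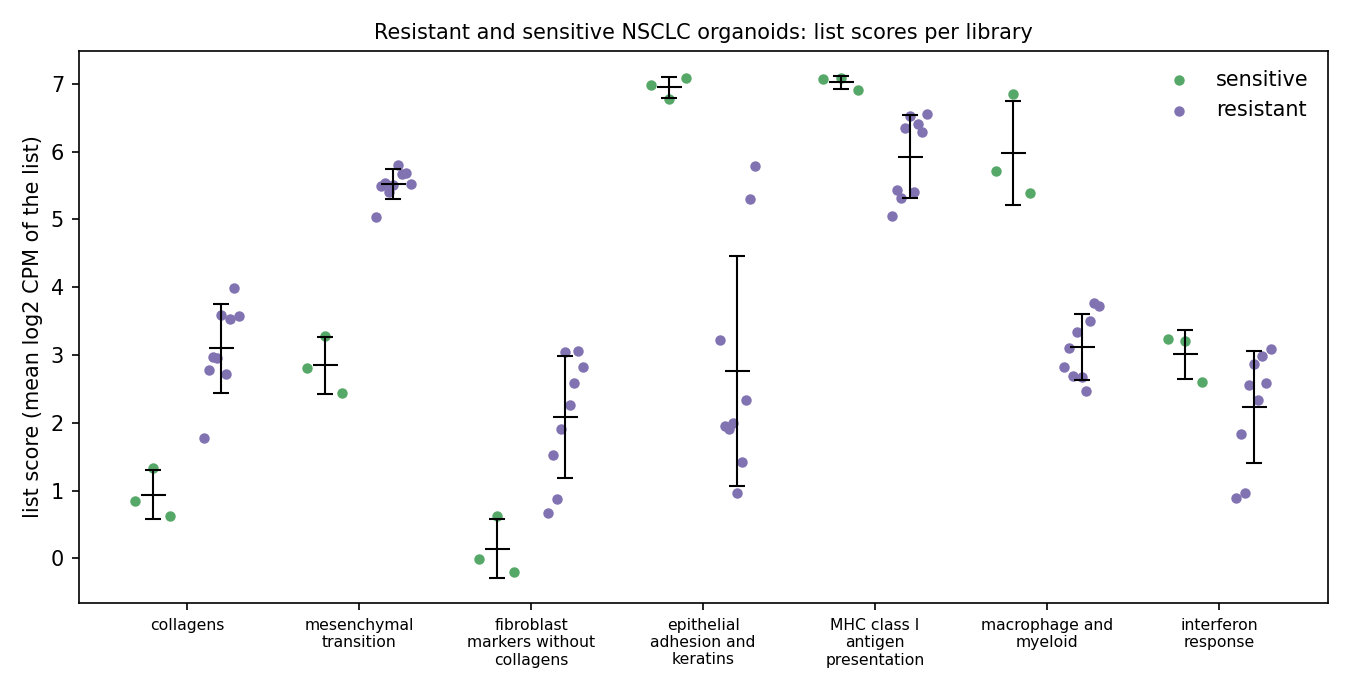
Each point is the score of a library (mean log2 CPM over the tested genes of the list named on the horizontal axis) in sensitive (green, n = 3) and resistant organoids (purple, n = 9), and bars are mean ± SD. The collagen score was 0.94 ± 0.36 in sensitive and 3.10 ± 0.66 in resistant libraries.

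Epithelial adhesion and keratin genes fell in 21 of 27 cases and rose in 0, with a median log2 fold change of -3.19 (fry adjusted p = 0.00349; adjusted p = 0.449 with an estimated correlation). Resistant libraries 8 and 9 stood apart, with epithelial scores of 5.30 and 5.79 against 0.97 to 3.22 in the other 7. Epcam was at 237 and 323 CPM in those libraries and at 30.3 CPM or less in the other resistant libraries. It was at 575 ± 32.5 CPM in sensitive and did not pass the test over all libraries (adjusted p = 0.0774, edgeR). Without resistant libraries 6, 8 and 9 its adjusted p was 3.92e-04, and over all alternatives it ran from 3.92e-04 to 0.148. Alveolar type 2 genes were lower in 13 of 23 cases and higher in 0 (fry adjusted p = 9.25e-04; adjusted p = 0.413 with an estimated correlation), Cebpa and Napsa among them. Club and goblet genes were lower in 7 of 16 cases and higher in 1 (fry adjusted p = 0.00452; adjusted p = 0.523 with an estimated correlation), with Scgb3a1 at 279.8 ± 146 CPM in sensitive and 1.3 ± 2.86 in resistant. Gut endoderm genes were lower in 8 of 14 cases and higher in 0 (fry adjusted p = 0.00284; adjusted p = 0.449 with an estimated correlation). Pigr, Mal2, Krt23, Ltf, Itga2, Sftpb and Ceacam1 were, with Cxcl5, the largest falls by the rule. The call of Pigr was lost without sensitive library 1, 2 or 3 or resistant library 7, that of Ltf without any of these or resistant libraries 1 to 6, and those of Sftpb and Ceacam1 without sensitive library 3.

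Antigen presentation and inflammatory genes were lower in resistant organoids. Of 21 MHC class I genes 8 fell and 0 rose (fry adjusted p = 0.0151; adjusted p = 0.554 with an estimated correlation). Without sensitive library 1 the fry adjusted p of this list was 0.071, and over all fry alternatives it ran from 0.0111 to 0.071. H2-K1, a class I heavy chain gene, fell from 2662 ± 106 to 834 ± 469 CPM (log2 fold change -1.67 ± 0.44 SE, adjusted p = 0.0102) and H2-D1 from 371 ± 35 to 96.8 ± 43.9 CPM. These genes belong to a family of near-identical members, so reads could be split between them. B2m fell from 1842 ± 40.6 to 876 ± 403 CPM (log2 fold change -1.07 ± 0.37 SE, adjusted p = 0.0353), a call lost without sensitive library 1, 2 or 3 or resistant library 3 or 6. Ifngr1, the interferon gamma receptor gene, fell from 127 ± 58 to 46 ± 16.7 CPM, while the interferon response list, with 13 lower and 2 higher of 52, did not pass (fry adjusted p = 0.231). Over all fry alternatives the adjusted p of the interferon response list ran from 0.0366 to 0.447, and camera with a preset correlation gave 0.0168. Checkpoint ligand genes were lower in 12 of 22 cases and higher in 0 (fry adjusted p = 9.25e-04; adjusted p = 0.413 with an estimated correlation). Cd274, which encodes PD-L1, was at 76.8 ± 44.2 CPM in sensitive and 24.4 ± 14.6 in resistant (log2 fold change -1.66 ± 0.57 SE, adjusted p = 0.0344), and its call was lost without sensitive library 1 or 2. Chemokine and cytokine genes fell in 22 of 38 cases and rose in 1 (fry adjusted p = 0.00249; adjusted p = 0.449 with an estimated correlation), with Cxcl5, a neutrophil attractant, going from 3724 ± 1088 to 105 ± 101 CPM. Macrophage and myeloid genes fell in 17 of 25 cases and rose in 0 (fry adjusted p = 1.43e-04; adjusted p = 0.395 with an estimated correlation). Adgre1 went from 167 ± 73 to 14.1 ± 6.44 CPM, and Ptprc, a pan-leukocyte gene, from 61.2 ± 40.3 to 14 ± 8.58 CPM. Whether fewer macrophages account for the falls of checkpoint ligand, chemokine and MHC class II genes was not tested.

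**Figure D3:**
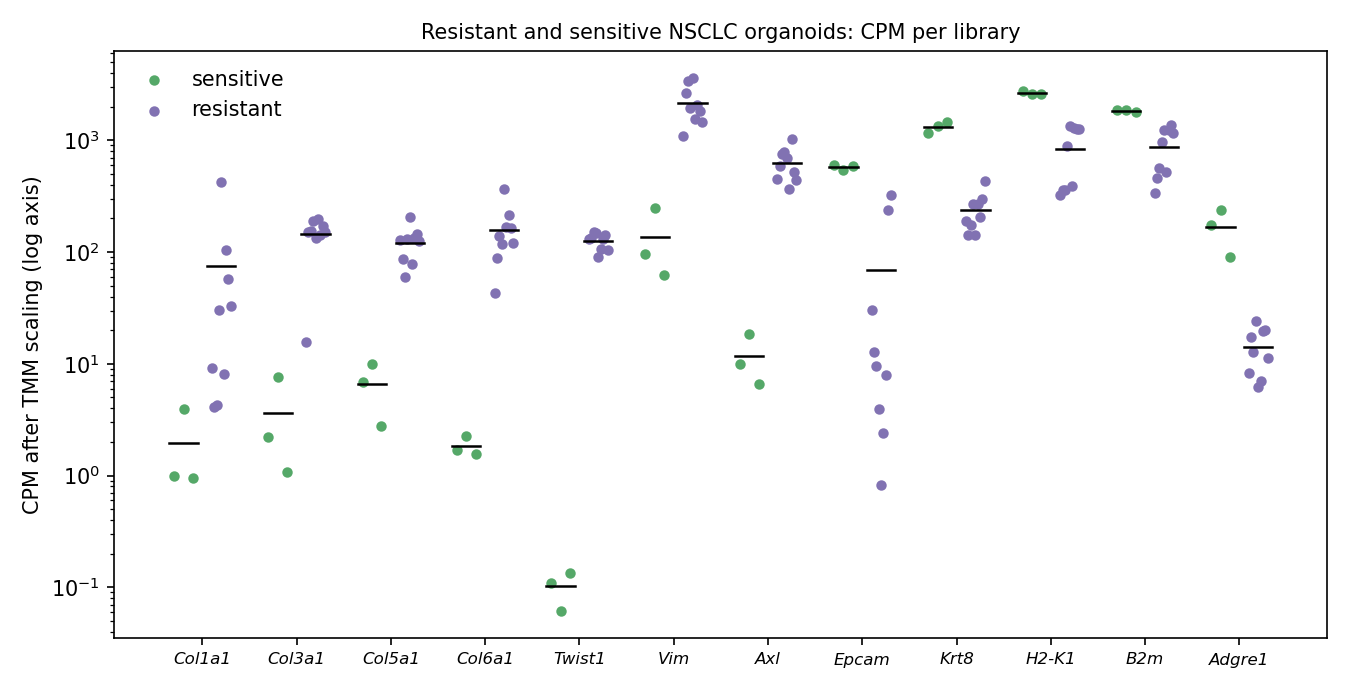
Each point is a library's CPM after TMM scaling (log axis) for a gene named on the horizontal axis, in sensitive (green, n = 3) and resistant organoids (purple, n = 9), and black lines are group means. Twist1 was 0.102 CPM on average in sensitive and 126 in resistant, and H2-K1 2662 and 834.

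Within the 9 resistant libraries, the collagen score was set against 7 other list scores. Libraries 2 and 3, and 8 and 9, were closer to each other than the other pairs (Spearman 0.988 and 0.986 against 0.917 to 0.975), and the permutation takes all 9 as separate. The collagen score rose with the score of fibroblast markers without collagens (Pearson r = 0.857, exact permutation p = 0.00173, adjusted 0.00606; Spearman rho = 0.85, exact p = 0.00607, adjusted 0.0213), and r was 0.73 without libraries 1 and 8, those farthest from the median. The TGF-beta pathway score gave r = 0.876 (exact permutation p = 0.00172, adjusted 0.00606; rho = 0.95, exact p = 3.53e-04, adjusted 0.00247) and 0.873 without those libraries. For the interferon response score r was 0.762 (exact permutation p = 0.0139, adjusted 0.0242; rho = 0.733, exact p = 0.0311, adjusted 0.0726) and 0.666 without them. Over the 6 libraries with Y-linked reads the values of r were 0.851, 0.87 and 0.796 (exact p = 0.025, 0.00694 and 0.0361). With libraries 2 and 3, and 8 and 9, each averaged to 1 value (n = 7), r was 0.902, 0.854 and 0.882 (exact p = 0.00417, 0.0117 and 0.00397, adjusted 0.00972, 0.0205 and 0.00972), and rho 0.857, 0.929 and 0.821 (exact p = 0.0238, 0.00675 and 0.0341, adjusted 0.0556, 0.0236 and 0.0597). With medians over genes in place of means, r was 0.712, 0.545 and 0.684 and none of the 3 relations passed after adjustment. For the mesenchymal, epithelial and proliferation scores r was 0.663, 0.335 and 0.00107, and none passed (exact permutation p = 0.0612, 0.367 and 0.998, adjusted 0.0857, 0.428 and 0.998). Spearman rho was 0.367, 0.2 and 0.0833 (exact p = 0.336, 0.613 and 0.843, adjusted 0.471, 0.716 and 0.843), and r without libraries 1 and 8 was -0.136, 0.409 and 0.503. Over the 6 libraries with Y-linked reads r was 0.91, -0.788 and -0.125 (exact permutation p = 0.0306, 0.107 and 0.783, not adjusted). The mesenchymal and epithelial relations thus depended on which libraries were taken. MHC class I scores fell into 2 separate sets, 5.05 to 5.44 in 4 libraries and 6.29 to 6.55 in 5. That relation was computed and counted among the 7, but a pooled r over 2 sets is not read here.

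Between the comparisons, which share no libraries, 13312 genes were tested in both. Of these 919 were higher in NSCLC and in resistant organoids, against 907 for independent lists, and 639 were lower in both, against 505. Among opposite calls there were 537 genes lower in NSCLC and higher in resistant (independent lists 525) and 774 genes higher in NSCLC and lower in resistant (872). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.103.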

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

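The 2 counts over sample splits were planned before the data were examined; the other tests in this part were chosen after the results were seen. Among 259 values tested for a library far from the rest of its group of 4 NSCLC or 9 resistant libraries, 17 stood out. Independent values with a Gaussian spread would give about 12.95. The values are CPM, some near the level of single counts, and the genes share libraries. The 12.95 is therefore only a rough guide, no excess is read from the 17, and single cases carry little weight.

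In NSCLC, library 1 was lowest for Itga2 at 222 CPM and for Ifngr1 at 45.6 CPM, and highest for S100a8 at 0.691 CPM. NSCLC library 3 was highest for Hspa1a at 428 CPM and for Snai2 at 0.008 CPM, and lowest for Lox at 0 CPM. NSCLC library 4 was highest for Col1a2 at 0.028 CPM, Adamts2 at 0.014 CPM and Fgf10 at 0.007 CPM, and lowest for Mmp3 at 0.035 CPM, and library 2 was lowest for Fbn1 at 0.007 CPM; these values lie at or near the level of a few counts. Among resistant libraries, library 1 was lowest for Col3a1 at 15.7 CPM, Mrc2 at 55.2 CPM and Pdgfrb at 2.68 CPM, against group medians of 153, 372 and 26.7 CPM. Library 3 was lowest for Col5a2 at 0.531 CPM and highest for Col26a1 at 0.133 CPM, and library 9 highest for Cebpa at 59.3 CPM.

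None of the other splits of the libraries that were tried gave as many differing genes in either comparison. This takes each library as a separate unit, which the labels do not show. It cannot tell the named group difference from depth, sex-linked reads or anything else that followed the groups. In the NSCLC comparison 1 of 35 splits gave as many genes, the real one with 10655, and the highest of the others gave 8. In the resistant comparison 1 of 100 drawn splits gave as many, the real one with 5380, and the highest of the others gave 359.

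Mesenchymal and collagen genes were higher and epithelial genes lower in resistant organoids. Fibroblasts in place of tumour cells would lower genes of tumour cells by about as much as the epithelial list, whose median log2 fold change was -3.19. The 146 genes outside every list with a log2 fold change of at least 5 in NSCLC over normal and at least 1 CPM in sensitive had a median of -2.48 (SD 2.20 over genes) in resistant over sensitive, with 106 of them below -1 and 27 above 0, so these values do not decide between fewer tumour cells and a change within them. Fibroblast scores were 0.666 and 0.876 in 2 resistant libraries and 1.52 to 3.06 in the other 7, against -0.197 to 0.630 in sensitive. Mesenchymal scores were 5.03 to 5.81 over all resistant libraries, against 2.44 to 3.28 in sensitive. In those 2 libraries this argues against fibroblasts, as scored by these markers, as the whole source of the mesenchymal rise. Fibroblasts could supply collagen reads, but the values do not single them out. The collagen score rose with fibroblast markers over the resistant libraries (Pearson r = 0.857), and 3 of the 25 markers are also in another list. It also rose with the TGF-beta (r = 0.876) and interferon response scores (r = 0.762). With median scores the fibroblast relation did not pass (r = 0.712, adjusted p = 0.105, exact permutation). Dcn, chosen after its values were seen, was at 5.78 to 41.3 CPM in resistant and 3.58 to 5.91 CPM in sensitive. These ranges overlap. A change within tumour cells that goes with the resistance named by the labels stays open and untested.

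MHC class I genes were lower in resistant organoids. Fewer macrophages as the whole cause is argued against by the sensitive libraries, where the macrophage score ranged over 1.46 and the MHC class I score over 0.169. Lyz2, abundant in macrophages and alveolar type 2 cells and chosen after its values were seen, was at 1223 to 2591 CPM in sensitive and 89.1 to 954 CPM in resistant. A weaker interferon response could be a cause. The interferon response list did not pass the main test (fry adjusted p = 0.231). Over fry alternatives its adjusted p ran from 0.0366 to 0.447, and camera with a preset correlation gave 0.0168. The call thus depends on the setting, and the MHC class I scores of the resistant libraries fell into 2 sets, so the values here do not decide it. The resistance named by the labels stays open as an untested biological difference.

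Collagen and fibroblast genes were lower in NSCLC than in normal organoids, and depth differed with the group. With all libraries thinned to the smallest total the collagen score difference was -4.63, so depth is argued against. Of the 21 collagen genes called lower, 15 were highest in normal library 2, which also had the highest fibroblast score, against 37.9% of the genes called lower outside every list; among macrophage markers called lower it was 16 of 18. This is consistent with fibroblasts in the normal cultures as a source of part of the difference, with Dcn at 9.67 to 18.5 CPM in normal and 0 to 0.0579 CPM in NSCLC, though macrophages follow the same library. A difference between tumour and normal epithelium stays open.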

How the results depend on the processing

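The thinned libraries, the setting without resistant libraries 6, 8 and 9 and the averaging of resistant libraries 2 and 3 and 8 and 9 were chosen after seeing the data. No named gene, list or collagen score difference that passed its test changed direction under the settings in this part. Of the 10655 NSCLC calls, 8555 (80.3%) were kept in thinned libraries, and of the 5380 resistant calls 4624 (85.9%) without libraries 6, 8 and 9, with 0 calls of opposite sign in either. Thinning ended the list call of cholesterol genes (fry adjusted p = 0.0966), and leaving out libraries 6, 8 and 9 those of fibroblast, p53 and smooth muscle genes (0.0518 to 0.061). At a fold change of at least 2 there were 3697 genes higher and 4000 lower in NSCLC, and 454 genes higher and 413 lower in both comparisons (377 and 242 for independent lists), a stricter rule by construction. At an adjusted p under 0.01, 1479 genes were higher and 1559 lower in resistant. Leaving out each library in turn gave 4490 to 5339 genes higher and 4092 to 5144 lower in NSCLC, and 1765 to 2867 higher and 1859 to 2694 lower in resistant, lowest when a sensitive library was left out, which leaves 2. Lists that passed numbered 25 to 29 in NSCLC and 14 to 23 in resistant over these settings, against 27 and 21 with all libraries, and the collagen score differences ran from -4.47 to -3.72 and from 1.92 to 2.33. Camera with an estimated correlation passed 0 lists in either comparison, and the cause was not tested. Camera with a preset correlation of 0.01 ended 8 list calls in NSCLC and 5 in resistant. In resistant it also passed the proliferation (camera adjusted p = 0.00117), interferon response (0.0168) and lymphocyte lists (0.0404). Averaging the 2 close pairs kept 3 relations of the collagen score past the threshold by Pearson r, and by Spearman rho the fibroblast relation was lost (adjusted p = 0.0556, exact permutation). Median scores in place of means left 0 of 3 relations of the collagen score past the threshold; the cause was not tested. Leaving out single libraries ended the calls of 4 named genes and 3 lists in NSCLC (cholesterol, endothelial and chemokine) and of 10 named genes and 7 lists in resistant. Which direction held more genes depended on the setting. In NSCLC more genes were lower at a fold change of at least 2, with DESeq2, limma-voom, thinned libraries, upper quartile scaling or library totals only, and in resistant with RLE scaling, limma-voom, no filter, a replicate block, adjusted p under 0.01, or without sensitive library 1 or 3 or resistant library 9. There were 4681 genes higher and 5758 lower in NSCLC under upper quartile scaling and 4721 and 5585 with library totals only, and 2645 and 2712 in resistant under RLE scaling. In the scaling alternatives, cholesterol genes in NSCLC and alveolar type 1 genes in resistant lost their list calls under upper quartile scaling.

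Replicate numbers did not pair the samples: correlations of same-numbered libraries were -0.00772, 0.0208 and -0.0212 for normal and NSCLC and 0.145, 0.146 and -0.0863 for sensitive and resistant, and not every library correlated best with its own number. With a replicate block, which uses only the numbers present in both groups, there were 4438 genes higher and 4328 lower in NSCLC and 1914 higher and 2191 lower in resistant. Under it 16 NSCLC lists and 16 resistant lists passed, 8516 of the 10655 NSCLC calls and 3425 of the 5380 resistant calls were kept, and the resistant collagen score difference was 1.57 (exact p = 0.25, the smallest that 3 pairs can give). The block uses fewer libraries. Among named genes it ended the calls of 1 in NSCLC and 5 in resistant, and added those of 1 and 6. It ended the calls of 11 NSCLC lists (basement membrane, collagen receptor, alveolar type 1, MHC class II, chemokine, proliferation, cholesterol, smooth muscle, endothelial, macrophage and mesothelial; adjusted p from 0.0653 to 0.153). In resistant it ended those of 7 lists (collagen, basement membrane, NF-kB, p53, YAP, smooth muscle and neuroendocrine; 0.0577 to 0.52). Lists without genes of other lists lost 2 calls in NSCLC (collagen receptor and WNT) and 3 in resistant (alveolar type 1, p53 and YAP). Changes of 2-fold were mostly missed in the simulations. The simulations changed far fewer genes than were called in the data, so their adjusted threshold was stricter than the real one.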

Other observations

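The list tests in this part were planned before the data were examined, and the test of Y-linked reads was chosen after the result was seen. Other lists moved in the resistant comparison. NF-kB target genes fell in 10 of 22 cases and rose in 1, with Cfb and C3 lower (fry adjusted p = 0.00279; adjusted p = 0.449 with an estimated correlation). Over all fry alternatives the adjusted p of that list ran from 7.03e-04 to 0.0732, and its call was lost with a replicate block. MHC class II genes fell in 5 of 8 cases, with H2-Aa at 64.4 ± 4.25 CPM in sensitive and 4.68 ± 3.3 in resistant (fry adjusted p = 0.0048; adjusted p = 0.523 with an estimated correlation). Targets of p53 (3 higher and 10 lower of 30), targets of YAP (7 and 4 of 23), basal genes (1 and 7 of 18), alveolar type 1 genes (3 and 8 of 19), smooth muscle genes (1 and 0 of 7) and neuroendocrine genes (3 and 1 of 7) passed fry with adjusted p from 0.00575 to 0.0367, and had adjusted p of 0.621 to 0.808 with an estimated correlation. Each of these 6 calls was lost without sensitive library 1 (adjusted p from 0.0515 to 0.207) and without sensitive library 3 (0.0643 to 0.103), and some without other libraries. Proliferation (14 higher and 0 lower of 38), TGF-beta, WNT, hypoxia, NRF2, RAS, cholesterol, ciliated, endothelial, lymphocyte, heat shock, collagen receptor, matrix protease, interferon receptor and high plasticity lists did not pass, and the mesothelial list had 4 genes tested, too few for a test. Of these, the TGF-beta, lymphocyte, collagen receptor, matrix protease, interferon receptor and high plasticity lists passed in some fry alternative (lowest adjusted p from 0.00584 to 0.0492). Camera with a preset correlation passed the proliferation (adjusted p = 0.00117) and lymphocyte lists (0.0404).

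In the NSCLC comparison, collagen processing (6 higher and 13 lower of 29), basement membrane (4 and 18 of 35), matrix protease (6 and 16 of 28), mesenchymal (1 and 14 of 21), MHC class II (0 and 5 of 9), chemokine (8 and 11 of 36), smooth muscle (1 and 7 of 14), endothelial (2 and 7 of 15) and mesothelial lists (1 and 3 of 7) were lower on balance, with fry adjusted p from 2.92e-04 to 0.0362. Collagen receptor (6 and 4 of 14, median log2 fold change 0.25 and mean -0.02), WNT target (8 and 3 of 21), cholesterol (12 and 4 of 24) and heat shock lists (18 and 1 of 25) were higher on balance, with fry adjusted p from 4.26e-04 to 0.0362. All of these had adjusted p of 0.342 or more with an estimated correlation. TGF-beta, basal, interferon, interferon receptor, checkpoint, NF-kB, YAP, NRF2, lymphocyte and neuroendocrine lists did not pass. Of these, the interferon receptor, NF-kB, YAP, lymphocyte and neuroendocrine lists passed in some fry alternative (lowest adjusted p from 7.07e-04 to 0.0461).

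Sex-linked reads separated libraries within the resistant group and separated the normal from the NSCLC group. Resistant libraries 6, 8 and 9 held Xist at 19.4, 47.5 and 43.2 CPM and 0 reads of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, all chosen after values were seen, while the other 6 resistant libraries and the 3 sensitive libraries held Y-linked reads and Xist under 1 CPM. Normal libraries held Xist at 605 to 708 CPM and 0 Y-linked reads, and the 4 NSCLC libraries held Xist at 0.0562 to 0.175 CPM and Y-linked reads at 0.0161 to 2.1 CPM. The hypothesis that Y-linked reads in the resistant cultures may come from leukocytes was tested against Ptprc over the 6 resistant libraries with such reads. On the log2 scale r was 0.834 (exact permutation p = 0.0403) and rho 0.6 (exact permutation p = 0.242). Without libraries 1 and 2 r was -0.308, but the libraries left spanned Ptprc of only 10.9 to 15.9 CPM, so that r says little. In sensitive libraries 3, 1 and 2, Y-linked reads of 12.4, 20.5 and 63.8 CPM went with Ptprc of 30.7, 46.1 and 107 CPM. In resistant libraries 6, 9 and 8, Xist of 19.4, 43.2 and 47.5 CPM went with Ptprc of 5.43, 11.8 and 14.6 CPM. NSCLC library 2, by contrast, held Y-linked reads at 2.1 CPM with Ptprc of only 0.121 CPM. These orders were not tested. The resistant relation of Y-linked reads rests on libraries 1 and 2, and the source cannot be told from these values.

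Resistant libraries 2 and 3 held Fos, an immediate early gene chosen after its values were seen, at 463 and 741 CPM, against 8.33 to 79.7 CPM in the other resistant libraries.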
